A study of Homo sapiens with 26 samples.

How the data were processed

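Total RNA was measured in sorted macrophages and cardiomyocytes, 26 samples in 8 groups, with libraries made by a stranded total RNA kit per the labels' protocols. The deposited values are whole-number counts of reads per gene, in 3 tables for Biowire macrophages (19206 genes), digested control macrophages (18771 genes) and Biowire cardiomyocytes (21991 genes). Per the submitters' processing notes, the tools were STAR 2.7.9a, HTSeq 0.11.0, DESeq2 and R 4.3.2, with the genome build hg19. The strand setting of the counting is not given in the sources used here. The deposited normalized tables were not used. Genes are named by their symbols as deposited, and 28 names in the cardiomyocyte table had been turned into dates, match no list and are not named. The tables hold 0 mitochondrially encoded genes, so that list was not measured. Genome coordinates are not used here. Digestion and sorting by CD14 and CD45 came before RNA extraction, and the labels give the same protocol for the control cells, so transcripts of CD14 and PTPRC (CD45) belong to the proteins that were used for selection. The digestion mix held flavopiridol, an inhibitor of transcription, per the labels' protocols.

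Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr, a quasi-likelihood F test (two-sided) and Benjamini-Hochberg adjustment at 0.05 in each of 10 comparisons. Each fit held all groups of its table, which share 1 estimate of the spread: 3 comparisons of Biowire macrophages, 3 of digested controls and 1 of cardiomyocytes. The difference between the Biowire and digested settings was tested as an interaction on the 17919 genes shared by both tables, in 1 fit of the 18 libraries with a mean for each of 6 groups, and levels were not compared across tables by a test. The design, the alternatives and 37 gene lists were fixed before the data were examined. Lists with at least 5 measured genes were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated per list. The calls kept with an estimated correlation are named as such beside each list. fry was run beside camera. It tests whether a list's genes move one way, without setting them against other genes. Marker levels are summed CPM, compared by exact permutation tests on log2(CPM + 1), and 3 against 3 libraries cannot go below p = 0.1. Groups at 0 counts were given a floor of 3 counts over the group, and ratios with 1 to 3 counts a 95% counting interval.

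Genes are named by a rule. For the Biowire macrophage and cardiomyocyte comparisons it takes the 8 largest rises and 8 largest falls among genes past adjusted p = 0.05, with no overlap between the libraries of the groups (which chance gives 10% of genes for 3 against 3) and at least 5 CPM in the higher group. For the digested and interaction comparisons it takes 4 and 4. The interactions carry no condition on overlap, and their minimum of 5 CPM is read in the compared Biowire groups. Up to 4 members with the smallest p are taken from each described list. Some genes that the rule takes are not reported here. CD14, PTPRC and CSF1R are always named in macrophages, and TNNT2, ACTN2, MYH6, MYH7, MYL2 and MYL7 in cardiomyocytes. Genes named by clone, small RNAs and genes that mark sex were left out. A gene of a list that falls outside the rule, such as C1QA in FB+MF macrophages, was picked after its values were seen.

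The tests were tried on simulated counts with the real means and library sizes and 200 changed genes. For Biowire CM+FB+MF against MF (13952 genes), 8.96%, 49.3% and 77.3% of genes changed 1.5, 2 and 4 times were recovered, with 5.26% false calls. For the digested CM+FB+MF against MF (12960 genes) the shares were 47.8%, 82.1% and 97.0% with 7.93% false, for its interaction (14381 genes) 13.4%, 58.2% and 83.3% with 2.83% false, and for the cardiomyocytes (16046 genes) 50.7%, 73.1% and 92.4% with 7.10% false. A planted list was called in each, and 0 of 20 random lists by camera. The simulated genes were drawn independently, so this does not test camera on lists of correlated genes. The 200 changed genes are far fewer than the 5249 called in the real Biowire CM+FB+MF against MF comparison. The shares recovered and false may differ where many genes change. These simulations were added after a first run on the real counts. Pairs of replicates were compared by chi-square for duplicate libraries, and every pair differed by more than sampling noise (chi-square per degree of freedom 2.48 to 40.4). Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, only the compared groups in the fit, a minimum log2 fold change of 1, the replicate number as a block, each library left out in turn, and for marker levels a pseudocount of 10 or the most abundant gene left out. A correction for transcript length, with lengths from GENCODE transcripts of another genome build matched by symbol, a count without genes of other cell types, the interferon-stimulated list with each library left out, and Biowire macrophage replicates 2 and 3 alone were added after seeing the data.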

Results

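RNA was sequenced from 26 samples of human embryonic stem cell (hESC) derived cells in 8 groups. Macrophages from the hES2 line (MF) and cardiomyocytes from the ESI17 line (CM) had been built with FB cells into Biowires, engineered cardiac microtissues. FB is read here as fibroblasts, which the labels do not spell out. The macrophages were sorted on day 14 from Biowires of macrophages alone, of fibroblasts and macrophages (FB+MF), or of all 3 cell types (CM+FB+MF), with n = 3 libraries per group. Control macrophages of the same 3 combinations, also n = 3 each, are labelled as digested cells with a 40 min digestion and no day of culture. Cardiomyocytes were sorted on day 3 from CM+FB and CM+FB+MF Biowires, with n = 4 per group. Nothing states that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

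Depth was 8265064 to 13665322 counts per library in Biowire MF, 10668086 to 12426918 in Biowire FB+MF and 6983800 to 8041669 in Biowire CM+FB+MF macrophages. The digested controls held 10132651 to 12717157 (MF), 10275678 to 10829127 (FB+MF) and 10802612 to 12272562 (CM+FB+MF) counts. The cardiomyocyte libraries held 27256342 to 29452933 without macrophages and 12604684 to 30936910 with them, the lowest being CM+FB+MF replicate 4. Levels are CPM, counts scaled to each library's total, as mean ± SD, and fold changes are log2 values ± SE from the TMM-normalized fit. Floors for groups at 0 (3 counts over the group) and ratio intervals cover counting error only.

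Markers of each cell type, on lists fixed before the data were examined, gave the makeup of the sorted libraries. Macrophage markers summed to 13356 ± 1017 CPM in Biowire MF, 18071 ± 818 in FB+MF and 19885 ± 749 in CM+FB+MF macrophages, and to 17246 ± 528, 16966 ± 346 and 16979 ± 738 CPM in the digested MF, FB+MF and CM+FB+MF controls. Cardiomyocyte markers summed to 2155 ± 880 CPM in Biowire CM+FB+MF macrophages against 53.6 ± 24.7 in FB+MF, a 40.2-fold difference (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries allow). In the digested CM+FB+MF controls they summed to 376 ± 109 CPM against 43.5 ± 4.35 in FB+MF, 8.63-fold (exact p = 0.1). Without TTN, the most abundant of these markers, the log2 differences went from 5.35 to 7.55 and from 3.04 to 4.35. Fibroblast markers differed by 1.22-fold between Biowire FB+MF and MF macrophages (719 ± 46.1 against 591 ± 63.9 CPM) and by 5.40-fold between the digested groups (1565 ± 380 against 290 ± 12.4 CPM), each with exact p = 0.1. Leaving out the most abundant marker took the log2 differences from 0.29 to 0.91 (SPARC) and from 2.40 to 1.81 (FN1). In the cardiomyocyte libraries, macrophage markers summed to 60.7 ± 25.04 CPM with macrophages and 8.11 ± 0.607 without, 7.49-fold (exact p = 0.0286, the smallest that 4 against 4 allow), beside cardiomyocyte markers at 144231 ± 3038 and 152336 ± 7538 CPM. Fibroblast markers there were 6321 ± 1552 and 4839 ± 1230 CPM (exact p = 0.2).

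**Figure D1:**
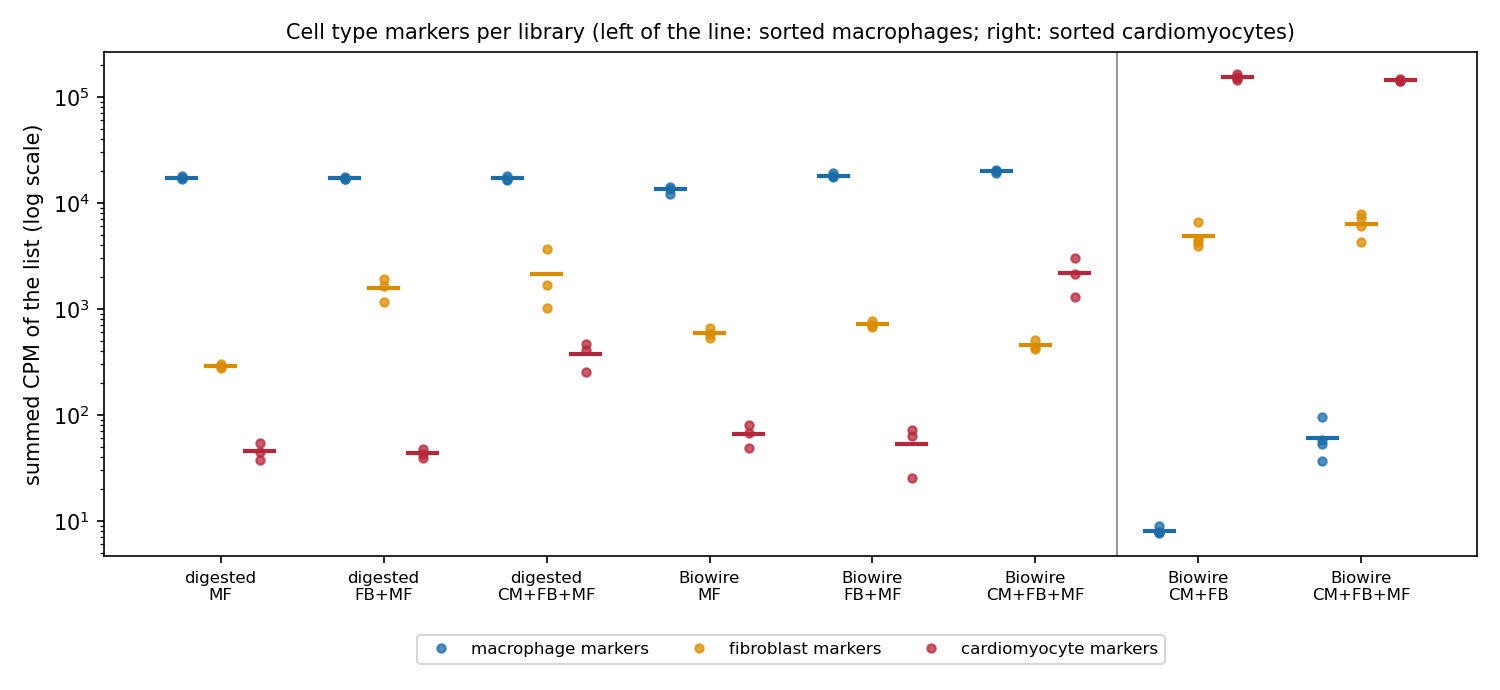
Summed CPM of the macrophage, fibroblast and cardiomyocyte markers (log axis) in each of the 26 libraries, by group, with points for libraries and bars for group means. Cardiomyocyte markers averaged 2155 CPM in Biowire CM+FB+MF macrophages, 376 CPM in the digested CM+FB+MF controls and 65.3 CPM or less in the macrophage groups without cardiomyocytes.

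The first comparison asked how macrophages in a tissue with fibroblasts differed from macrophages alone, both after 14 days in Biowires. Genes that move cholesterol out of the cell rose in the FB+MF macrophages, led by the exporters ABCG1 (3.68 ± 0.19) and ABCA1 (2.18 ± 0.15) and the phospholipid transfer protein PLTP (2.86 ± 0.14). The scavenger receptors STAB1 (3.79 ± 0.22) and CD163 (1.22 ± 0.13), the complement component C1QA (1.80 ± 0.26), the Fc receptor FCGR3A (2.60 ± 0.26) and the secreted matrix protein SPP1 (2.85 ± 0.17) rose as well (n = 3 per group). edgeR called 860 of 13952 genes, 562 higher and 298 lower in FB+MF, and 389 of them differed by at least 1 on the log2 scale. Genes with a mean CPM in CM+FB cardiomyocytes at least 8 times that in digested macrophages alone, or called in a digested comparison, made up 18.1% of the 562 higher calls. Such genes were 1140 of the 13952 tested and 19 of the 298 lower calls. The count was 549 without FB+MF replicate 2 and 553 without MF replicate 3.

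Of the 16 measured cholesterol efflux and lipid handling genes, 13 rose (13 adjusted over the list alone). Camera gave the list adjusted p = 5.47e-41, and adjusted p = 0.000862 with an estimated correlation, which kept the call. Among them was CD36 (1.16 ± 0.09), a fatty acid and apoptotic cell receptor. Efferocytosis genes, which serve the uptake of dying cells, moved likewise: of 25, 12 rose (15 adjusted over the list alone). They included PROS1 (1.24 ± 0.13), a bridge to phosphatidylserine, and LRP1 (0.89 ± 0.09), an engulfment receptor. By camera the list had adjusted p = 3.28e-17, and adjusted p = 0.0146 with an estimated correlation, which kept the call. Matrix remodelling genes (18 measured, 7 rose and 1 fell (9 and 1 adjusted over the list alone)) included the elastase MMP12 (2.53 ± 0.25) and the urokinase receptor PLAUR (1.52 ± 0.15), while the collagenase cathepsin CTSK fell (-2.10 ± 0.11). As a list these genes had camera adjusted p = 2.27e-06, and adjusted p = 0.0493 with an estimated correlation, which kept the call. Of 17 growth factor and tissue repair genes, 4 rose (5 adjusted over the list alone). They included SPP1 and TGFBI (1.07 ± 0.20). The set test gave camera adjusted p = 3.99e-05, and adjusted p = 0.0310 with an estimated correlation, which kept the call.

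Macrophage markers rose in FB+MF (20 measured, 11 rose (13 adjusted over the list alone)). Over the whole list, camera gave adjusted p = 9.57e-15, but adjusted p = 0.0534 with an estimated correlation. CD14, the lipopolysaccharide co-receptor whose protein was used for the sort, went from 115 ± 26.4 to 402 ± 51.5 CPM (1.84 ± 0.17). PTPRC, which encodes the other sort antigen CD45, had a log2 fold change of -0.01 ± 0.10 (edgeR adjusted p = 0.986), and CSF1R, the receptor for macrophage colony-stimulating factor, one of 0.68 ± 0.23 (adjusted p = 0.118). CSF1R passed without MF replicate 1 (1.09, adjusted p = 0.0014) and with no filter on low counts (0.69, adjusted p = 0.0172). It also passed with Biowire replicates 2 and 3 alone (1.19, adjusted p = 4.45e-06). Genes of tissue-resident macrophages included rises of VSIG4 (3.14 ± 0.27) and STAB1 and a fall of the iron exporter SLC40A1 (-1.26 ± 0.12). Of 18, 7 rose and 1 fell (8 and 2 adjusted over the list alone) (camera adjusted p = 3.31e-13, but adjusted p = 0.123 with an estimated correlation). Their summed CPM was 3486 to 4720 in the Biowire MF and 5974 to 7315 in the Biowire FB+MF libraries. In digested macrophages alone, a separate table, it was 11329 to 11708, and levels were not tested across tables. Antigen-presenting MHC class II genes (12 measured, 3 rose and 1 fell (6 and 1 adjusted over the list alone)) included HLA-DPB1 (0.86 ± 0.16) and HLA-DRA (0.55 ± 0.12). For these genes together, camera gave adjusted p = 0.00258, but adjusted p = 0.402 with an estimated correlation. Fibroblast markers moved with the group too: of 14, 3 rose (4 adjusted over the list alone). They included MFAP5 (2.57 ± 0.20) and COL1A2 (1.23 ± 0.12). With camera the list had adjusted p = 3.27e-06, but adjusted p = 0.0913 with an estimated correlation.

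Cholesterol synthesis genes moved opposite to those of efflux: of 19, 8 fell (16 adjusted over the list alone). Tested with camera, the list had adjusted p = 2.05e-09, but adjusted p = 0.175 with an estimated correlation. DHCR7, which makes the last step to cholesterol, fell (-1.17 ± 0.24), with adjusted p = 0.0593 without FB+MF replicate 2 and 0.0563 without FB+MF replicate 3. HMGCS1, an early enzyme of the pathway, fell (-0.73 ± 0.17), with adjusted p = 0.0981 without FB+MF replicate 2 and 0.0696 without MF replicate 1. Of 24 glycolysis and hypoxia genes, 5 rose (8 adjusted over the list alone). They included the glucose transporter SLC2A3 (2.62 ± 0.23) and LDHA (0.68 ± 0.10). Set against other genes, the list had camera adjusted p = 2.35e-05, but adjusted p = 0.0534 with an estimated correlation. Of 23 fatty acid oxidation genes, 4 rose (5 adjusted over the list alone). They included PDK4 (1.15 ± 0.17) and ACADVL (0.54 ± 0.11). The list had camera adjusted p = 0.00258, but adjusted p = 0.163 with an estimated correlation. Interferon-stimulated genes (26 measured, 2 fell (10 adjusted over the list alone)) had a median of -0.96 (camera adjusted p = 1.96e-08, but adjusted p = 0.430 with an estimated correlation), and their summed CPM ranged from 3270 to 10139 between the 3 MF libraries and from 1974 to 6030.0 between the FB+MF libraries. Without FB+MF replicate 1, the library at 6030.0 CPM, 22 fell, without MF replicate 1 7 fell, and without any other library of these groups 1 fell. Oxidative phosphorylation genes (median -0.04, camera adjusted p = 0.409), lysosome genes (median 0.06, camera adjusted p = 0.807) and cardiomyocyte markers (camera adjusted p = 0.807) did not pass.

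The largest rises by the naming rule were of MMP7, a matrix metalloprotease, with a ratio of 116 (95% counting interval 31.8 to 963), the C1q-associated receptor CD93 (5.63 ± 0.35), the interleukin receptor chains IL2RA (5.33 ± 0.65) and IL7R (5.11 ± 0.64), the coagulation factor subunit F13A1 (5.32 ± 0.51), PCOLCE2 (5.12 ± 0.39), DCHS1 (4.88 ± 0.43) and AEBP1 (4.50 ± 0.72). The largest falls were of the interferon-induced chemokine CXCL10 (-5.42 ± 1.04), the lymph node homing receptor CCR7 (-4.28 ± 0.75), RASSF6 (-3.90 ± 0.71), TRPM1 (-3.72 ± 0.47), NEURL3 (-3.69 ± 0.71), SYNE2 (-3.50 ± 0.39), STON1-GTF2A1L (-3.37 ± 0.58), which overlaps a neighbouring gene and is uncertain, and ADCY8 (-3.33 ± 0.58). CCR7 had adjusted p = 0.0520 without MF replicate 2, and NEURL3 had adjusted p = 0.0511 by DESeq2.

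The next comparison set macrophages from tissues with all 3 cell types against macrophages alone. CD14 went from 115 ± 26.4 to 969.9 ± 63.6 CPM (3.07 ± 0.17) and CSF1R from 168 ± 68.1 to 1121 ± 119.6 CPM (2.72 ± 0.25), and PTPRC rose by 0.77 ± 0.10 (n = 3 per group). STAB1 (7.08 ± 0.26), F13A1 (8.71 ± 0.56), the elastase MMP12 (7.01 ± 0.30) and SPP1 (4.94 ± 0.19) rose, the last to 13380.0 ± 1199 CPM. CTSK (-4.89 ± 0.13), the stress cytokine GDF15 (-4.32 ± 0.25) and the cystine transporter SLC7A11 (-5.20 ± 0.49) fell. edgeR called 5249 of 13952 genes, 37.6%, with 2490 higher and 2759 lower, and 2433 differed by at least 1 on the log2 scale. Genes at least 8 times higher in CM+FB cardiomyocytes than in digested macrophages alone, or called in a digested comparison, made up 409 of the 2490 higher calls (16.4%), and 13.6% of the 2285 higher calls against FB+MF. Such genes were 1140 of the 13952 tested, 137 of the 2759 lower calls, and 146 of the 2664 lower calls against FB+MF.

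Of 20 macrophage markers, 15 rose and 1 fell (15 and 1 adjusted over the list alone). They included FCGR3A (4.68 ± 0.28), FCGR2A (1.69 ± 0.11) and the mannose receptor MRC1 (1.55 ± 0.13). Camera gave the list adjusted p = 1.69e-10, but adjusted p = 0.101 with an estimated correlation. Of 18 resident macrophage genes, 11 rose and 3 fell (11 and 4 adjusted over the list alone), with rises of PLTP (3.96 ± 0.15) and F13A1 and a fall of SLC40A1 (-1.93 ± 0.12). With camera the list had adjusted p = 6.24e-08, but adjusted p = 0.223 with an estimated correlation. MHC class II genes (12 measured, 10 rose and 1 fell (10 and 1 adjusted over the list alone)) included HLA-DPA1 (1.22 ± 0.13) and HLA-DPB1 (1.42 ± 0.16). By camera the list had adjusted p = 0.000390, but adjusted p = 0.273 with an estimated correlation. Of 25 efferocytosis genes, 14 rose and 2 fell (17 and 2 adjusted over the list alone). They included the phosphatidylserine-sensing kinase MERTK (1.66 ± 0.11), LRP1 (1.00 ± 0.09) and the integrin ITGB5 (1.21 ± 0.11). The set test gave camera adjusted p = 2.73e-06, but adjusted p = 0.0762 with an estimated correlation. Cholesterol efflux and lipid handling genes (16 measured, 7 rose and 2 fell (7 and 2 adjusted over the list alone)) included ABCG1 (4.59 ± 0.20), ABCA1 (3.80 ± 0.16) and SREBF1 (1.84 ± 0.21). As a list these genes had camera adjusted p = 3.74e-05, but adjusted p = 0.0762 with an estimated correlation. Cholesterol synthesis genes (19 measured, 15 fell (17 adjusted over the list alone)) included CYP51A1 (-1.45 ± 0.17) and LSS (-1.13 ± 0.14). Over the whole list, camera gave adjusted p = 5.27e-06, but adjusted p = 0.273 with an estimated correlation. Growth factor and tissue repair genes (17 measured, 6 rose and 3 fell (6 and 3 adjusted over the list alone)) held rises of VEGFA (2.86 ± 0.22) and HBEGF (3.12 ± 0.27). For these genes together, camera gave adjusted p = 0.0326, but adjusted p = 0.136 with an estimated correlation. The same libraries held cardiomyocyte markers at 2155 ± 880 CPM.

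Of 24 glycolysis and hypoxia genes, 18 rose and 1 fell (19 and 1 adjusted over the list alone). Tested with camera, the list had adjusted p = 8.25e-16, and adjusted p = 0.0124 with an estimated correlation, which kept the call. The genes that rose included the glucose transporters SLC2A1 (4.97 ± 0.22) and SLC2A3 (3.66 ± 0.24), LDHA (1.94 ± 0.10) and the collagen prolyl hydroxylase P4HA1 (1.65 ± 0.11). Of 42 oxidative phosphorylation genes, 32 fell (36 adjusted over the list alone). They included SDHB (-0.92 ± 0.11) and ATP5B (-0.70 ± 0.09). Set against other genes, the list had camera adjusted p = 1.9e-06, but adjusted p = 0.0762 with an estimated correlation. Of 23 fatty acid oxidation genes, 3 rose and 6 fell (3 and 6 adjusted over the list alone), and the list did not pass (median -0.15, camera adjusted p = 0.392). Lysosome genes (34 measured, 3 rose and 25 fell (3 and 28 adjusted over the list alone)) included the cathepsin CTSS (-1.32 ± 0.09) and the proton pump subunits ATP6V1A (-1.47 ± 0.10) and ATP6V0D2 (-1.45 ± 0.10). The list had camera adjusted p = 3.97e-09, but adjusted p = 0.190 with an estimated correlation. Of 19 oxidative stress genes, 1 rose and 15 fell (2 and 15 adjusted over the list alone). They included GPX4 (-1.51 ± 0.10), NQO1 (-2.63 ± 0.20) and HMOX1 (-1.75 ± 0.13). Camera gave the list adjusted p = 9.9e-08, but adjusted p = 0.101 with an estimated correlation. Of 21 p53 and apoptosis genes, 1 rose and 14 fell (1 and 14 adjusted over the list alone), with a fall of MDM2 (-2.15 ± 0.11) and a rise of BCL2L11 (2.03 ± 0.23). The set test gave camera adjusted p = 0.000263, but adjusted p = 0.101 with an estimated correlation. Interferon-stimulated genes (26 measured, 24 fell (25 adjusted over the list alone)) included IFI27 (-2.10 ± 0.30) and OAS1 (-1.72 ± 0.28). By camera the list had adjusted p = 2.11e-06, but adjusted p = 0.448 with an estimated correlation. The 3 MF libraries held 3270, 10139 and 7014 CPM of these genes.

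Cardiomyocyte transcripts stood out among the genes higher in CM+FB+MF macrophages. Of 19 cardiomyocyte markers, 18 rose (18 adjusted over the list alone), with a median of 8.59, or 7.53 with genes at 0 in a group set at their bound (camera adjusted p = 2.25e-30, but adjusted p = 0.0638 with an estimated correlation). MYH7, a ventricular myosin heavy chain, stood at 241 ± 55.6 CPM (10.02 ± 0.39). By the naming rule the largest rises were those of the neuronal pentraxin NPTX1 (at least 1619-fold, 152 ± 26.0 CPM against 0), the troponin TNNT2 (at least 1223-fold), the atrial light chain MYL7 (at least 507-fold), the calcium release channel RYR2 (at least 389-fold), ALOX5AP, which serves leukotriene synthesis (at least 316-fold), HSPB7 (at least 307-fold), MYL3 (at least 252-fold) and DES (at least 239-fold). The largest falls were those of APOD (at least 149-fold lower), TRPM1 (at least 77.1-fold), CCR7 (at least 70.6-fold), SLCO4C1 (at least 59.4-fold), PANX3 (at least 52.7-fold), SPATS1 (at least 45.0-fold), IRX6 (at least 41.8-fold) and DAPL1, with a ratio of 0.00156 (95% counting interval 3.95e-05 to 0.00873). Fibroblast markers did not pass as a list (14 measured, 5 rose and 3 fell (7 and 3 adjusted over the list alone), camera adjusted p = 0.324). Among them COL1A2 rose (0.73 ± 0.12) and SPARC fell (-1.97 ± 0.17).

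Macrophages from CM+FB+MF tissues were then compared with those from FB+MF tissues, which differ by the presence of cardiomyocytes. SLC2A1 (5.05 ± 0.22) and the hypoxia-induced EGLN3 (5.19 ± 0.35) and NDRG1 (2.43 ± 0.15) rose, as did CSF1R (2.04 ± 0.24), CD14 (1.24 ± 0.16), PTPRC (0.77 ± 0.10), STAB1 (3.29 ± 0.21) and the hyaluronan receptor LYVE1 (3.19 ± 0.31). CTSK (-2.79 ± 0.12), the saposin precursor PSAP (-1.51 ± 0.12), the lipid carrier APOE (-1.38 ± 0.11) and the fatty acid binding protein FABP4 (-2.98 ± 0.30) fell (n = 3 per group). edgeR called 4949 of 13952 genes, 2285 higher and 2664 lower, and 2033 differed by at least 1 on the log2 scale.

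Of 24 glycolysis and hypoxia genes, 17 rose and 2 fell (18 and 2 adjusted over the list alone) (camera adjusted p = 9.83e-12, and adjusted p = 0.0443 with an estimated correlation, which kept the call). Of 34 lysosome genes, 1 rose and 27 fell (1 and 30 adjusted over the list alone). They included CD63 (-1.02 ± 0.09). The list had camera adjusted p = 1.56e-12, but adjusted p = 0.178 with an estimated correlation. Of 42 oxidative phosphorylation genes, 31 fell (32 adjusted over the list alone). They included SDHB (-0.93 ± 0.11) and ATP5A1 (-0.85 ± 0.11). As a list these genes had camera adjusted p = 1.24e-06, but adjusted p = 0.102 with an estimated correlation. Fatty acid oxidation genes (23 measured, 1 rose and 12 fell (1 and 12 adjusted over the list alone)) included ACAA2 (-0.99 ± 0.11) and, rising, PDK4 (1.04 ± 0.16). Over the whole list, camera gave adjusted p = 0.0116, but adjusted p = 0.342 with an estimated correlation. Of 19 oxidative stress genes, 1 rose and 15 fell (2 and 15 adjusted over the list alone). They included NQO1 (-2.48 ± 0.19) and GPX4 (-1.37 ± 0.10). For these genes together, camera gave adjusted p = 2.32e-10, but adjusted p = 0.102 with an estimated correlation. Macrophage markers (20 measured, 10 rose and 2 fell (10 and 2 adjusted over the list alone)) included FCGR2A (1.08 ± 0.11) and AIF1 (1.55 ± 0.18). With camera the list had adjusted p = 0.00122, but adjusted p = 0.504 with an estimated correlation. Resident macrophage genes (18 measured, 9 rose and 5 fell (9 and 5 adjusted over the list alone)) included CD163L1 (3.18 ± 0.27). Tested with camera, the list had adjusted p = 0.00256, but adjusted p = 0.504 with an estimated correlation. MHC class II genes (12 measured, 6 rose (6 adjusted over the list alone)) included HLA-DPA1 (0.80 ± 0.13) and CIITA (0.85 ± 0.23). Set against other genes, the list had camera adjusted p = 0.0245, but adjusted p = 0.522 with an estimated correlation. Of 21 p53 and apoptosis genes, 1 rose and 11 fell (1 and 11 adjusted over the list alone) (camera adjusted p = 8.02e-05, but adjusted p = 0.102 with an estimated correlation). Of 26 interferon-stimulated genes, 1 rose and 10 fell (1 and 12 adjusted over the list alone) (camera adjusted p = 0.0178, but adjusted p = 0.645 with an estimated correlation). The FB+MF libraries held 6030.0, 1974 and 2233 CPM of these genes and the CM+FB+MF libraries 2105, 1405 and 1225. Without FB+MF replicate 1, 3 fell and the set test did not pass (camera adjusted p = 0.266), and without CM+FB+MF replicate 3, 4 fell (camera adjusted p = 0.0951). Without CM+FB+MF replicate 2, 4 fell with camera adjusted p = 0.0338.

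Efferocytosis and lipid genes were split in this comparison and did not pass as lists. Of 25 efferocytosis genes, 6 rose and 5 fell (6 and 5 adjusted over the list alone), with MERTK higher (1.34 ± 0.11) and CD36 lower (-0.98 ± 0.09). Camera gave the list adjusted p = 0.322. Of 16 cholesterol efflux and lipid handling genes, 5 rose and 10 fell (5 and 10 adjusted over the list alone), with ABCA1 higher (1.62 ± 0.14). By camera the list had adjusted p = 0.0674. Of 19 cholesterol synthesis genes, 6 fell (6 adjusted over the list alone). They included ACAT2 (-1.11 ± 0.21). The set test gave camera adjusted p = 0.0674. Of 19 cardiomyocyte markers, 18 rose (18 adjusted over the list alone), with a median of 8.81, or 7.62 with the bounds (camera adjusted p = 9.93e-39, and adjusted p = 0.0449 with an estimated correlation, which kept the call). They and other heart muscle genes led the rises: MYL7 (at least 538-fold), ACTC1 (at least 471-fold), RYR2 (at least 412-fold), HSPB7 (at least 325-fold), MYL3 (at least 267-fold), MYH6 and MYH7, with NPTX1 at a ratio of 5153 (95% counting interval 924 to 203581). The falls were led by the olfactory receptors OR8A1 (at least 65.2-fold lower), OR8G5, OR8B8 and OR8B2, related genes whose reads could be split between copies and whose values are uncertain, by PANX3 (at least 56.0-fold) and MMP7 (at least 53.9-fold), and by GSG1 (ratio 0.00503 (95% counting interval 0.000127 to 0.0282)) and GLP2R.

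**Figure D2:**
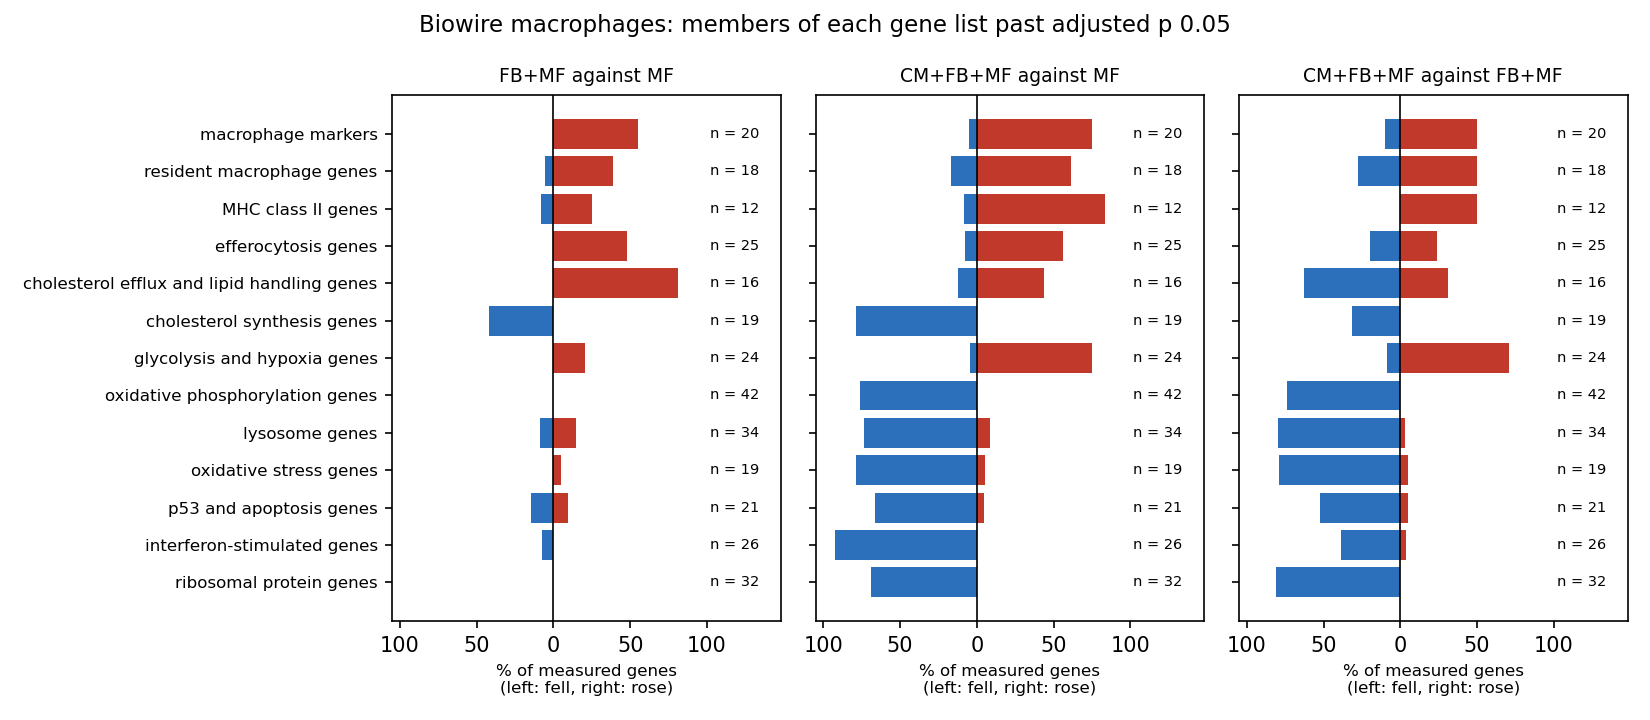
Percentage of the measured genes of each list that rose (right, red) or fell (left, blue) past adjusted p 0.05 in the 3 comparisons of Biowire macrophages, with n the genes measured. Lipid handling genes rose in FB+MF against MF (13 of 16), glycolysis and hypoxia genes rose in both CM+FB+MF comparisons (18 and 17 of 24), and oxidative phosphorylation genes fell in both (32 and 31 of 42).

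The digested controls gave the background of the same measurements in the same 3 combinations of cells. Transcripts typical of the other cell types were higher in the combined controls than in macrophages alone. In FB+MF controls the fibroblast genes FN1 (7.57 ± 0.65), which encodes fibronectin, and COL6A3 (3.56 ± 0.45) rose. POSTN (at least 952-fold), CTGF (at least 413-fold), BGN (at least 336-fold) and VCAN (at least 295-fold), all genes of matrix proteins, led the list. In CM+FB+MF controls FN1 (8.06 ± 0.65), POSTN (at least 1236-fold, 113 ± 75.9 CPM), CTGF (at least 638-fold), BGN (at least 448-fold) and VCAN (at least 432-fold) rose, and so did MYH6, the atrial myosin heavy chain, with a ratio of 2674 (95% counting interval 479 to 105640.0), and ACTN2 (3.97 ± 0.30), n = 3 per group.

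edgeR called 349 of 12960 genes between CM+FB+MF and MF controls, 349 higher and 0 lower. 152 genes were lower at an unadjusted p under 0.05, and DESeq2 called 366 higher and 0 lower. Between FB+MF and MF controls it called 207 higher and 0 lower, with 118 lower at an unadjusted p under 0.05 and 264 higher and 0 lower by DESeq2. Between CM+FB+MF and FB+MF controls it called 31 higher and 0 lower, with 120 lower at an unadjusted p under 0.05 and 40 higher and 0 lower by DESeq2. The count of 207 was 123 without FB+MF replicate 1, and 132, 99 and 132 without MF replicates 1, 2 and 3. The count of 31 was 72 without CM+FB+MF replicate 2, 20 and 19 without FB+MF replicates 1 and 3, and 53 with no filter on low counts.

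Of 16 fibroblast markers, 16 rose (16 adjusted over the list alone) in CM+FB+MF controls, with a median of 5.28, or 5.12 with the bounds (camera adjusted p = 3.21e-84, and adjusted p = 0.0156 with an estimated correlation, which kept the call), and 13 rose (16 adjusted over the list alone) in FB+MF controls, with a median of 4.73, or 4.58 with the bounds (camera adjusted p = 1.79e-99, and adjusted p = 0.0182 with an estimated correlation, which kept the call). Of 16 cardiomyocyte markers, 15 rose (16 adjusted over the list alone) in CM+FB+MF against MF, with a median of 8.34, or 5.54 with the bounds (camera adjusted p = 1.01e-177, and adjusted p = 0.00167 with an estimated correlation, which kept the call). Against FB+MF, 14 rose (16 adjusted over the list alone), with a median of 8.04, or 5.44 with the bounds (camera adjusted p = 0 as computed, too small to be held as a number, and adjusted p = 0.000106 with an estimated correlation, which kept the call). ACTC1 (at least 272-fold), MYL4 (at least 86.8-fold), NEBL (at least 65.0-fold) and MYH6 (ratio 1251 (95% counting interval 346 to 10335)) led that comparison. Smooth muscle markers (7 measured, 5 rose (5 adjusted over the list alone) in CM+FB+MF against MF) included TAGLN (2.82 ± 0.27) and ACTA2 (3.07 ± 0.35). As a list these genes had camera adjusted p = 2.92e-18, and adjusted p = 0.0428 with an estimated correlation, which kept the call. In FB+MF against MF 2 rose (4 adjusted over the list alone). Over the whole list, camera gave adjusted p = 2.72e-13, but adjusted p = 0.104 with an estimated correlation.

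The sort markers and CSF1R did not pass between the controls. CD14 had a log2 fold change of 0.02 ± 0.06 in CM+FB+MF against MF (380.5 ± 15.0 and 375 ± 17.7 CPM), PTPRC -0.03 ± 0.06 and CSF1R -0.05 ± 0.05, each with edgeR adjusted p = 0.999. In FB+MF against MF they were 0.05 ± 0.06, -0.08 ± 0.06 and -0.01 ± 0.05, and in CM+FB+MF against FB+MF -0.03 ± 0.06, 0.05 ± 0.06 and -0.04 ± 0.05. List medians in CM+FB+MF against MF were -0.03 for macrophage markers (camera adjusted p = 0.291), -0.03 for resident macrophage genes (camera adjusted p = 0.385), -0.03 for efferocytosis (camera adjusted p = 0.969), 0.01 for lipid handling (camera adjusted p = 0.931) and -0.01 for lysosome genes (camera adjusted p = 0.359). Of 23 glycolysis and hypoxia genes, 4 rose (6 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 2.84e-06, and adjusted p = 0.0428 with an estimated correlation, which kept the call). Growth factor and tissue repair genes (18 measured, 4 rose (4 adjusted over the list alone), camera adjusted p = 0.00270, but adjusted p = 0.0901 with an estimated correlation), matrix remodelling genes (16 measured, 4 rose (5 adjusted over the list alone), camera adjusted p = 0.000297, but adjusted p = 0.270 with an estimated correlation) and inflammatory cytokine genes (20 measured, 3 rose (5 adjusted over the list alone), camera adjusted p = 0.000541, but adjusted p = 0.286 with an estimated correlation) passed the set test beside the markers of other cells.

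Whether the Biowire and the digested differences themselves differed was tested as an interaction over 14381 genes, within which the 2 settings come from separate count tables. CD14 differed by 3.06 ± 0.19 in CM+FB+MF against MF, by 1.79 ± 0.19 in FB+MF against MF and by 1.27 ± 0.19 in CM+FB+MF against FB+MF. CSF1R differed by 2.79 ± 0.28 and 2.09 ± 0.28 in the comparisons with cardiomyocytes, and PTPRC by 0.80 ± 0.11 and 0.73 ± 0.11. In FB+MF against MF, PTPRC had 0.07 ± 0.11 (edgeR adjusted p = 0.830) and CSF1R 0.70 ± 0.27 (adjusted p = 0.190), or 1.11 (adjusted p = 0.000688) without Biowire MF replicate 1. CSF1R had 1.22 (adjusted p = 1.49e-05) with Biowire replicates 2 and 3 alone. STAB1 differed by 7.15 ± 0.29 and 3.79 ± 0.27, ABCG1 by 4.65 ± 0.25 and 3.89 ± 0.25, and ABCA1 by 3.75 ± 0.17 and 2.16 ± 0.17 in CM+FB+MF and FB+MF, each against MF. edgeR called 4482 genes for CM+FB+MF against MF (2068 with a higher and 2414 with a lower Biowire difference), 696 for FB+MF against MF (391 and 305) and 4081 for CM+FB+MF against FB+MF (1905 and 2176). Of these, 2205, 380 and 1820 differed by at least 1 on the log2 scale. With Biowire replicates 2 and 3 alone, added after seeing the data, the 696 became 1242, with 642 genes shared.

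For FB+MF against MF, 11 of 16 lipid handling genes (12 adjusted over the list alone) had a higher Biowire difference (camera adjusted p = 7.93e-37, and adjusted p = 1.9e-05 with an estimated correlation, which kept the call), as had 10 of 25 efferocytosis genes (14 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.01e-16, and adjusted p = 0.000499 with an estimated correlation, which kept the call) and 11 of 20 macrophage markers (13 adjusted over the list alone; camera adjusted p = 2.03e-17, and adjusted p = 0.0410 with an estimated correlation, which kept the call). CD93 (5.77 ± 0.43), F13A1 (5.40 ± 0.52), IL7R (5.34 ± 0.73) and IL2RA (5.31 ± 0.77) were the largest. For CM+FB+MF against MF, efferocytosis genes (13 higher and 2 lower of 25, 15 and 2 adjusted over the list alone; camera adjusted p = 3.17e-06, and adjusted p = 0.0394 with an estimated correlation, which kept the call) and glycolysis and hypoxia genes (14 higher and 1 lower of 24, 15 and 1 adjusted over the list alone; camera adjusted p = 6.24e-09, and adjusted p = 0.0392 with an estimated correlation, which kept the call) had higher Biowire differences. Oxidative phosphorylation genes (26 lower of 42, 31 adjusted over the list alone) had camera adjusted p = 7.92e-06, but adjusted p = 0.351 with an estimated correlation. Lysosome genes (3 higher and 22 lower of 34, 3 and 24 adjusted over the list alone) had camera adjusted p = 5.37e-09, but adjusted p = 0.271 with an estimated correlation. For CM+FB+MF against FB+MF, glycolysis and hypoxia genes (16 higher and 1 lower of 24, 16 and 1 adjusted over the list alone) had camera adjusted p = 4.79e-07, but adjusted p = 0.0710 with an estimated correlation.

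Fibroblast markers went the other way: 14 of 17 (14 adjusted over the list alone) had a lower Biowire difference in CM+FB+MF against MF (camera adjusted p = 3.81e-06, but adjusted p = 0.264 with an estimated correlation) and 9 (11 adjusted over the list alone) in FB+MF against MF (camera adjusted p = 1.65e-13, but adjusted p = 0.0515 with an estimated correlation). COL5A2 (-7.48 ± 1.06) was among them. The calls of COL1A1 and POSTN were lost without Biowire MF replicate 3, with adjusted p = 0.313 and 1.00 in CM+FB+MF against MF and 0.536 and 1.00 in FB+MF against MF. Cardiomyocyte markers had 4 of 19 higher in the Biowire setting (3 adjusted over the list alone) for CM+FB+MF against MF (camera adjusted p = 0.170). They included TTN (2.38 ± 0.46) and MYBPC3. NPTX1, ALOX5AP, ADAM8 and ABCB4 led the higher and POSTN, APOD, COL1A1 and CXCL11 the lower differences there. For CM+FB+MF against FB+MF these were NPTX1, IGF2, ID1 and CDH2, and OR8A1, OR8G5, MGST1 and OR8B8. Many of these rest on a group at or near 0, so no fold is given. OR8B8 (adjusted p = 0.0334) was lost without any 1 of 7 libraries, the highest adjusted p being 0.116 without digested CM+FB+MF replicate 1.

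The last comparison asked how cardiomyocytes differed when macrophages were in the tissue for 3 days. Cholesterol synthesis genes fell, with HMGCS1 (-1.19 ± 0.07) and DHCR7 (-1.04 ± 0.07) among them. Cell cycle genes rose, with the proliferation marker MKI67 (1.15 ± 0.08) and the mitotic kinase PLK1 (1.48 ± 0.12) among them. The libraries also held fibroblast markers, at 6321 ± 1552 CPM with macrophages and 4839 ± 1230 CPM without. Whether changes in this comparison came from cardiomyocytes or from other cells in the libraries was not tested for fibroblasts. IGF2, a growth factor of fetal tissue, went from 113 ± 9.23 to 629 ± 42.1 CPM (2.46 ± 0.08) and FNDC5, the irisin precursor, from 7.86 ± 1.02 to 49.8 ± 1.13 (2.65 ± 0.10). The feedback inhibitors of growth factor signalling SPRY4 (-2.92 ± 0.11; 145 ± 16.3 to 19.4 ± 3.26 CPM), DUSP4 (-3.80 ± 0.26) and DUSP6 (-1.98 ± 0.10) fell (n = 4 per group). edgeR called 2033 of 16046 genes, 1090 higher and 943 lower with macrophages, and 399 differed by at least 1 on the log2 scale, 272 higher and 127 lower.

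Of 19 cholesterol synthesis genes, 19 fell (19 adjusted over the list alone), with a median of -1.04 (camera adjusted p = 9.66e-81, and adjusted p = 0.000871 with an estimated correlation, which kept the call). Of 27 cell cycle genes, 24 rose (25 adjusted over the list alone), with a median of 0.97. They included CENPF (1.13 ± 0.10) and TPX2 (1.10 ± 0.09). Set against other genes, the list had camera adjusted p = 6.9e-39, and adjusted p = 0.0152 with an estimated correlation, which kept the call. Of 26 glycolysis and hypoxia genes, 17 rose and 1 fell (19 and 1 adjusted over the list alone). They included LDHA (1.18 ± 0.16), PDK1 (0.68 ± 0.08) and ALDOA (0.60 ± 0.08). For these genes together, camera gave adjusted p = 4.93e-14, but adjusted p = 0.158 with an estimated correlation. Of 43 oxidative phosphorylation genes, 23 rose (31 adjusted over the list alone), with a median of 0.25. They included NDUFB8 (0.26 ± 0.05) and COX7B (0.38 ± 0.07). With camera the list had adjusted p = 7.85e-09, but adjusted p = 0.517 with an estimated correlation. Over all genes of this comparison, fold change fell with transcript length (Spearman correlation -0.133). The oxidative phosphorylation genes are short, at a median of 715.5 bases against 1901 for all genes with a length. Interferon-stimulated genes (20 measured, 8 rose (10 adjusted over the list alone)) included IFIT1 (1.15 ± 0.11) and BST2 (1.03 ± 0.17). Tested with camera, the list had adjusted p = 1.09e-05, and adjusted p = 0.0495 with an estimated correlation, which kept the call. Fatty acid oxidation genes did not pass (23 measured, 2 rose and 1 fell (3 and 2 adjusted over the list alone), camera adjusted p = 0.513). Macrophage markers in these libraries were 60.7 ± 25.04 CPM with macrophages and 8.11 ± 0.607 CPM without.

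Genes of the contractile apparatus moved both ways. Of 46 sarcomere genes, 3 rose and 16 fell (6 and 20 adjusted over the list alone), with a median of -0.13. They included the skeletal actin ACTA1 (-1.31 ± 0.17), the M-band protein MYOM2 (-0.74 ± 0.08) and SYNPO2L (-0.60 ± 0.06). The list had camera adjusted p = 0.000230, but adjusted p = 0.409 with an estimated correlation. ACTN2 fell (-0.25 ± 0.05), as did MYH7 (-0.32 ± 0.09, edgeR adjusted p = 0.0388). MYH7 had adjusted p = 0.102 and 0.1003 without CM+FB replicates 1 and 3, and 0.0976, 0.0777 and 0.0928 without CM+FB+MF replicates 1, 3 and 4. A block for the replicate number gave MYH7 adjusted p = 0.0804. TNNT2 (0.04 ± 0.06), MYH6 (-0.08 ± 0.05), MYL2 (0.05 ± 0.08) and MYL7 (-0.08 ± 0.07) had adjusted p of 0.711, 0.418, 0.773 and 0.527. Cardiac stress genes (20 measured, 1 rose and 7 fell (3 and 9 adjusted over the list alone)) included the natriuretic peptide NPPA (-1.53 ± 0.09), ANKRD1 (-1.71 ± 0.09) and CTGF (-1.29 ± 0.07). Camera gave the list adjusted p = 8.9e-11, and adjusted p = 0.0495 with an estimated correlation, which kept the call. Smooth muscle markers (11 measured, 7 fell (7 adjusted over the list alone)) included MYH11 (-1.57 ± 0.09) and TAGLN (-0.81 ± 0.06). By camera the list had adjusted p = 3.56e-10, and adjusted p = 0.0495 with an estimated correlation, which kept the call.

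Lists of maturation and electrical function did not pass. Adult-type cardiomyocyte genes (22 measured, 3 rose and 4 fell (7 and 4 adjusted over the list alone), camera adjusted p = 0.874) held a rise of the mitochondrial creatine kinase CKMT2 (0.41 ± 0.05) and a fall of the gap junction gene GJA1 (-0.96 ± 0.08). Fetal-type genes (16 measured, 3 rose and 5 fell (4 and 5 adjusted over the list alone), camera adjusted p = 0.265) held IGF2, NPPA and the pacemaker channel HCN4 (-0.58 ± 0.05). Calcium handling genes (22 measured, 2 rose and 7 fell (5 and 7 adjusted over the list alone), camera adjusted p = 0.0610) held falls of CASQ2 (-0.73 ± 0.12), a calcium store protein, BIN1 (-0.83 ± 0.11), which shapes T-tubules, and STIM1 (-0.48 ± 0.07). Ion channel and conduction genes (25 measured, 4 rose and 4 fell (6 and 5 adjusted over the list alone), camera adjusted p = 0.973) held a rise of CACNA1G (0.62 ± 0.07). Extracellular matrix genes (25 measured, 3 rose and 6 fell (5 and 8 adjusted over the list alone), camera adjusted p = 0.158), cardiomyocyte markers (20 measured, 2 rose and 4 fell (6 and 5 adjusted over the list alone), camera adjusted p = 0.331) and fibroblast markers (19 measured, 2 rose and 1 fell (3 and 1 adjusted over the list alone), camera adjusted p = 0.206) did not pass either. All 15 measured macrophage markers rose (15 adjusted over the list alone; camera adjusted p = 2.09e-24, and adjusted p = 0.0418 with an estimated correlation, which kept the call). C1QA was at least 85.5-fold higher, C1QB had a ratio of 272 (95% counting interval 92.6 to 1320.2) and CD68 rose by 1.80 ± 0.21. Macrophage genes were also among the largest rises by the naming rule, with C1QC, SPP1 (5.05 ± 0.33), CD163 (4.92 ± 0.71), F13A1 (4.42 ± 0.78) and STAB1 (2.71 ± 0.53). The remaining largest falls were those of GALNT14 (-2.99 ± 0.27), VAT1L (-2.64 ± 0.18), DRP2 (-2.36 ± 0.24), SHROOM4 (-2.14 ± 0.10) and PIANP (-2.12 ± 0.24).

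**Figure D3:**
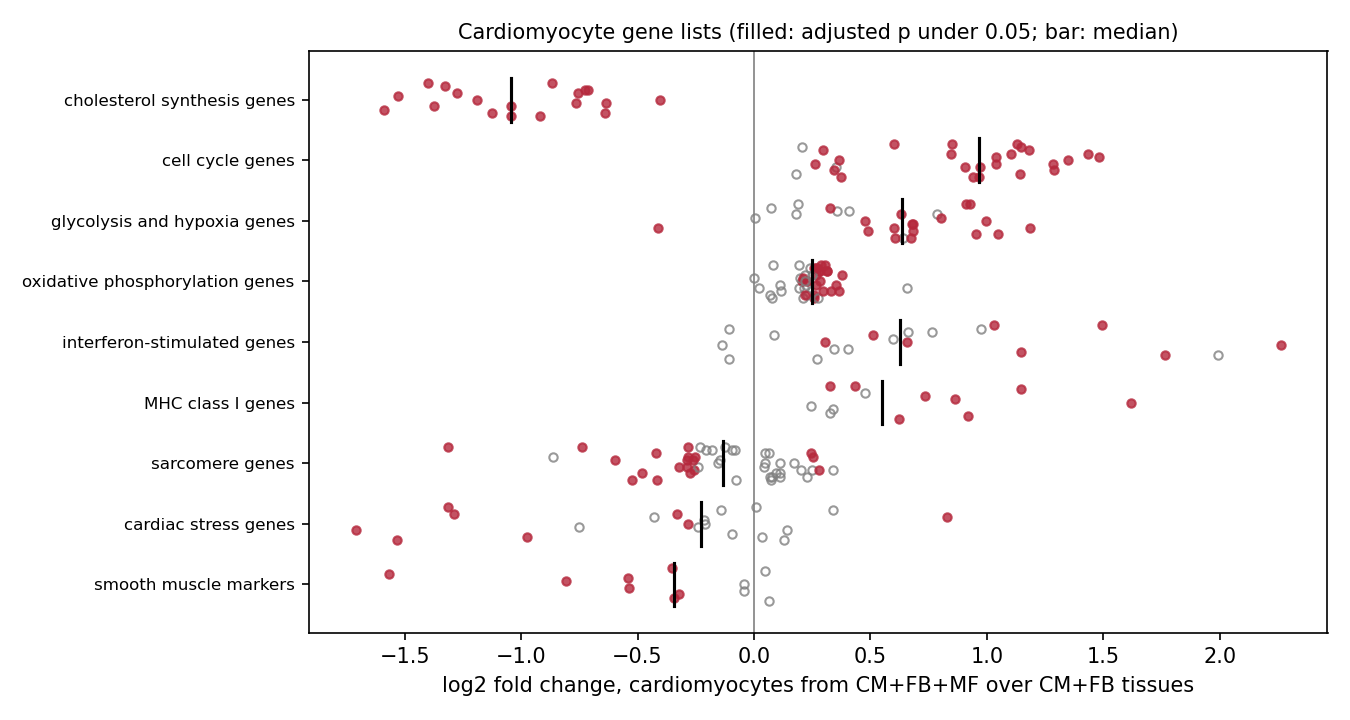
Log2 fold change of each gene (points) of 9 lists in cardiomyocytes from CM+FB+MF over CM+FB Biowires, filled where adjusted p is under 0.05, with a bar at the list median. All 19 cholesterol synthesis genes lie below 0 and 24 of 27 cell cycle genes passed above 0.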

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

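The tests of macrophages' own transcripts, of the same carry-over and of uptake were chosen only after their results were seen, and the others below before. In digested CM+FB+MF against MF macrophages 349 genes were higher and 0 lower by edgeR (152 lower at an unadjusted p under 0.05, 0 by DESeq2). RNA or cells of cardiomyocytes carried into the sorted macrophages may account for the cardiomyocyte part: 100% of 52 genes abundant in cardiomyocytes and near absent from macrophages were higher with cardiomyocytes, at a median of 0.275% of their cardiomyocyte level (quartiles 0.204% and 0.378%). Changes of the macrophages' own transcripts during the digestion stay open, since 7.74% of the 349 genes had 20 CPM or more in macrophages alone and no value tells carried RNA from a response there. This test first had a bound of 10% under which such changes were taken as excluded, and it was replaced after its result was seen, because a small share of expressed genes does not forbid a response in those genes.

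Cardiomyocyte transcripts in Biowire CM+FB+MF macrophages exceeded those of the digested controls by a ratio of 5.74 in summed marker CPM across 2 separate tables. Every Biowire library lay above every digested one, so the marker level was not that of the controls. The ratio gives the amount of carry-over only if the cardiomyocytes held the same marker levels in both settings. No sample is labelled as digested control cardiomyocytes, so this cannot be told. The excess was uneven between genes, with MYH6 at 421 and 80.8 CPM and ACTC1 at 41.1 and 26.4 CPM in the Biowire and digested groups. As a list the cardiomyocyte markers did not pass the interaction in CM+FB+MF against MF. The pattern is consistent with cardiomyocyte RNA entering as a whole, since 100% of 45 abundant cardiomyocyte genes were higher than in FB+MF macrophages, at a median share of 0.913% (quartiles 0.730% and 1.35%). Uptake of cardiomyocyte material by macrophages in the tissue cannot be told apart from more carry-over out of a dense tissue: 3 cardiomyocyte markers passed the test of the difference for CM+FB+MF against FB+MF, which both explanations allow, and no group analysed here separates them. Sorting on CD14 and CD45 should remove free cardiomyocytes, but not fragments bound to or inside macrophages.

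In cardiomyocytes with macrophages, cholesterol synthesis genes fell and cell cycle genes rose. Macrophage RNA in these libraries, at a median of 0.225% of its macrophage level (quartiles 0.165% and 0.358%), is argued against for both: 0% of the 24 cell cycle genes that passed rose by an amount within 2 times the expected carry-over, and the cholesterol synthesis median of -1.04 is far beyond the dilution of -0.0032 that such a share gives. The expected carry-over used macrophages of day 14 Biowires and of digested controls. No macrophage library is labelled day 3, so levels of macrophages on that day are not covered. By the same measure 50 of the 1090 higher calls (4.59%) lay within the expected carry-over, and 112 (10.3%) were genes at least 8 times higher in digested macrophages alone than in CM+FB cardiomyocytes, as were 758 of the 16046 tested. The shallow CM+FB+MF replicate 4 is not the cause either, as 97.7% of these genes (42 of 43) still passed without it. A response of the cardiomyocytes to macrophages, the group the design names, may account for the pattern, as may a different mix of cardiomyocyte states among the sorted cells, which was not tested. Fibroblast RNA in these libraries was not weighed. Fibroblast markers were at 6321 ± 1552 CPM with macrophages and 4839 ± 1230 CPM without (exact permutation p = 0.2).

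Other splits of the same libraries were counted for each number of changed genes. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real and highest other counts were 5249 and 0 for Biowire CM+FB+MF against MF, 860 and 36 for FB+MF against MF, 4949 and 0 for CM+FB+MF against FB+MF, and 349 and 0, 207 and 0, and 31 and 0 for the digested counterparts, the real split being the 1 with the most genes each time. For cardiomyocytes the real count was the highest (2033 against at most 21), 1 of 35 splits and so a share under 0.05. Splits deal only with the spread between libraries. If the replicates shared a culture, a chance difference between cultures stays open. For the interactions, 30 drawn splits exchanged the settings within each combination of cells. The settings may differ whatever the combination, and such a difference can add or hide calls in an exchanged split. These splits therefore cannot decide on chance. The real count was the highest in CM+FB+MF against MF (4482 against at most 2972, 1 of 30) and in CM+FB+MF against FB+MF (4081 against at most 1458, 1 of 30). Chance was not excluded in FB+MF against MF, where another split called several times as many genes (696 against 3373, 2 of 30). Which libraries that split exchanged was not examined.

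Differences between the Biowire and digested effects passed the interaction test for 4482, 696 and 4081 genes, in the order CM+FB+MF against MF, FB+MF against MF and CM+FB+MF against FB+MF. These were 31.2%, 4.84% and 28.4% of the genes tested. Of the 19 genes named by size or always in each Biowire comparison, 13, 12 and 8 differed. Most of the 19 were picked for a large Biowire change, which is part of the tested difference, so these counts are no separate support. CD14 differed by 3.06, 1.79 and 1.27, PTPRC by 0.80 and 0.73 in the first and last, and CSF1R by 2.79 and 2.09 in the same. Among the cardiomyocyte libraries 5 values in 60 groups of 4 stood far from the other 3, where chance gives about 1 in 20. The smooth muscle markers were at 2338 CPM in CM+FB replicate 2. C1QB was at 0.11 CPM in CM+FB replicate 4. DUSP4 was at 7.17 CPM in CM+FB replicate 1. VAT1L was at 3.44 CPM in CM+FB+MF replicate 1. MYH7 was at 9133 CPM in CM+FB+MF replicate 2.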

How the results depend on the processing

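The length correction, the removal of genes of other cell types, the interferon list with libraries left out and the use of Biowire replicates 2 and 3 alone were chosen after seeing the data. Over 311 named gene values and 4099 alternatives, 4025 kept direction and side of the threshold, 52 lost the call (18 values), 9 gained it (3 values) and 13 changed sign (7 values). Counts of changed genes with 1 library left out ranged from 4346 to 5092 (Biowire CM+FB+MF against MF), 549 to 844 (FB+MF against MF) and 3910 to 4378 (CM+FB+MF against FB+MF), from 266 to 486, 99 to 180 and 19 to 72 for the digested counterparts, from 3725 to 4640, 485 to 796 and 3240 to 4087 for the interactions, and from 1434 to 1905 for cardiomyocytes. A minimum log2 fold change of 1 gave 2433, 389 and 2033, then 2205, 380 and 1820 for the interactions and 399 for cardiomyocytes, by construction fewer. With no low-count filter digested CM+FB+MF against FB+MF gave 53, and the cause was not tested. DESeq2 gave 5526, 1211 and 5204 for the Biowire macrophages and 2369 for cardiomyocytes. Length correction gave 4973, 914, 4594 and 2009, and leaving out genes of other cell types 4673, 718, 4476 and 1884. With length correction 28 of 42 oxidative phosphorylation and 13 of 32 ribosomal protein genes fell in CM+FB+MF against MF. RLE factors changed the sign of 2 list medians, cardiomyocyte markers in digested FB+MF against MF and p53 genes in cardiomyocytes.

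With an estimated correlation the lists called went to 1, 4 and 2 (from 16, 14 and 14) in the Biowire macrophages, 4, 1 and 1 (from 9, 9 and 5) in the controls, 2, 3 and 0 (from 17, 15 and 13) in the interactions and 6 (from 13) in cardiomyocytes. Beside the 0 by camera, 4 lists had an unadjusted p under 0.05 and fry called 16. Without the most abundant gene the log2 differences were 7.55 and 4.35 (cardiomyocyte markers, Biowire and digested) and 0.91 and 1.81 (fibroblast markers). With 1 library left out they ranged from 4.89 to 5.68, 2.86 to 3.30, 0.22 to 0.37 and 2.24 to 2.60, with 2.43 to 2.89 for macrophage and 0.27 to 0.56 for fibroblast markers in cardiomyocytes.

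Values near 0 changed sign. PTPRC in Biowire FB+MF against MF was 0.0051 with no low-count filter and -0.058 to 0.054 with 1 library left out. With 1 control library left out, CD14 in CM+FB+MF against MF ranged from -0.027 to 0.069 and PTPRC from -0.093 to 0.0067, CSF1R in FB+MF against MF from -0.052 to 0.027, and CD14 from -0.070 to 0.019 and PTPRC from -0.013 to 0.084 in CM+FB+MF against FB+MF. MYL2 in cardiomyocytes ranged from -0.0015 to 0.116. Each was past the threshold in no such setting.

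The labels give replicate numbers but do not state that equal numbers pair the samples. Deviations of same-numbered libraries correlated at 0.00311 to 0.229 (all 9 pairs positive and 2 over 0.1; mean 0.0971, against -0.0478 for 18 pairs of different numbers) in Biowire macrophages, -0.205 to 0.298 (2 of 9) in controls and -0.138 to 0.186 (1 of 4) in cardiomyocytes. As a hint from the data, not the design, a library correlated best with its own number in 13 of 18 tries against another group, 4 of 18 and 3 of 8. Replicate 1 stood apart in all 3 Biowire macrophage groups: chi-square per degree of freedom was 18.2 to 32.2 against replicates 2 and 3, and 5.55 to 9.63 between those, and rRNA genes took 2.02% (CM+FB+MF), 0.838% (FB+MF) and 1.71% (MF) of its counts, more than in the other 2 of each group. With replicates 2 and 3 alone the Biowire counts were 5541, 1288 and 4705 (4705, 723 and 4094 shared with all libraries) and the interactions 5237, 1242 and 4397 (4157, 642 and 3602 shared), and the cause was not tested. With the replicate number as a block the counts were 5359, 861 and 5003, then 306, 187 and 25, then 4502, 645 and 4106 for the interactions, and 1680 for cardiomyocytes. Of these, 5092, 791, 4743, 303, 181, 25, 4240, 591, 3828 and 1632 genes were shared with the fit without the block. Of the named genes the block changed 1 call, MYH7 in cardiomyocytes (-0.31, adjusted p = 0.0804). The CM+FB+MF macrophage libraries were the shallowest, at 6983800 to 8041669 counts, and the effect of depth was not tested.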

Other observations

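The tests of the MYH7, TNNI3 and MYL2 shares were chosen only after its result was seen. Other gene lists moved in the Biowire macrophages. Immediate early and heat shock genes (25 measured in CM+FB+MF against MF, 14 rose and 5 fell (15 and 6 adjusted over the list alone)) included the transcription factor EGR1 (3.65 ± 0.33), the mRNA decay factor ZFP36 (3.55 ± 0.20) and the chaperones HSPA6 (2.16 ± 0.17) and HSPB1 (-1.42 ± 0.11). As a list these genes had camera adjusted p = 0.00101, but adjusted p = 0.423 with an estimated correlation. All groups were digested with flavopiridol. In FB+MF against MF 4 rose (6 adjusted over the list alone). They included NR4A1 (2.17 ± 0.48). With camera the list had adjusted p = 0.0129, but adjusted p = 0.587 with an estimated correlation. Unfolded protein and integrated stress genes in FB+MF against MF (23 measured, 4 rose (4 adjusted over the list alone)) included the chaperones HSPA5 (0.72 ± 0.19) and HSP90B1 (0.81 ± 0.14). Over the whole list, camera gave adjusted p = 0.0155, but adjusted p = 0.587 with an estimated correlation. In CM+FB+MF against FB+MF 1 rose and 9 fell (2 and 11 adjusted over the list alone), with DDIT3 (-2.54 ± 0.30) and TRIB3 (-2.67 ± 0.31) lower (camera adjusted p = 0.00284, but adjusted p = 0.504 with an estimated correlation). Ribosomal protein genes (32 measured in CM+FB+MF against MF, 22 fell (23 adjusted over the list alone)) included RPS19 (-0.71 ± 0.13). For these genes together, camera gave adjusted p = 0.00142, but adjusted p = 0.568 with an estimated correlation. With a correction for transcript length, added after seeing the data, 13 of them fell. Monocyte-derived macrophage genes did not pass there (camera adjusted p = 0.487), and S100A9 rose (4.46 ± 0.26) while CD52 fell (-3.81 ± 0.22). IL1B (4.31 ± 0.42) and CXCL3 (2.05 ± 0.20) rose within the inflammatory list, which did not pass (camera adjusted p = 0.0911).

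In cardiomyocytes with macrophages, histone genes of S phase rose beside the cell cycle genes: of 15, 10 rose (13 adjusted over the list alone). They included HIST1H1B (1.24 ± 0.15). Tested with camera, the list had adjusted p = 2.15e-09, but adjusted p = 0.233 with an estimated correlation. MHC class I genes (12 measured, 8 rose (10 adjusted over the list alone)) included HLA-C (0.62 ± 0.07), the immunoproteasome subunit PSMB8 (1.62 ± 0.27) and the peptide transporter TAP2 (0.86 ± 0.12). Set against other genes, the list had camera adjusted p = 8.18e-08, but adjusted p = 0.136 with an estimated correlation. Immediate early and heat shock genes (25 measured, 1 rose and 8 fell (1 and 10 adjusted over the list alone)) included EGR1 (-1.25 ± 0.21) and NR4A1 (-1.04 ± 0.16). The list had camera adjusted p = 0.000348, but adjusted p = 0.158 with an estimated correlation. Ribosomal protein genes (32 measured, 13 rose (28 adjusted over the list alone)) had a median of 0.23. Camera gave the list adjusted p = 1.07e-07, but adjusted p = 0.545 with an estimated correlation. Histone and ribosomal protein genes are short, at median lengths of 642.5 and 740 bases against 1901 for all genes. Fold change fell with transcript length in this comparison (Spearman correlation -0.133). Macrophage markers rose in the same libraries.

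A hypothesis concerns which cardiomyocytes the RNA in the macrophages came from. MYH7 made up 37.4 ± 4.72% of MYH6 plus MYH7 counts in Biowire CM+FB+MF macrophages on day 14 (n = 3), and 15.9 ± 2.09% and 13.8 ± 0.616% in the CM+FB and CM+FB+MF cardiomyocytes on day 3 (n = 4 each), with exact permutation p = 0.00606 (adjusted p = 0.0182 over 6 such tests) and all 3 libraries above all 8. TNNI3 made up 10.6 ± 3.14% of TNNI1 plus TNNI3 against 3.72 ± 0.556% and 3.30 ± 0.472%, also with exact p = 0.00606. By these shares the RNA may come from cardiomyocytes of another MYH6 and MYH7 makeup than the day 3 libraries. The other myosin pair does not bear this out: MYL2 made up 19.2 ± 2.25% of MYL2 plus MYL7, against 18.98 ± 1.16% and 20.4 ± 0.333% in the cardiomyocyte libraries (exact p = 0.679). The digested CM+FB+MF controls had a MYH7 share of 32.0 ± 1.06% and a MYL2 share of 2.53 ± 0.651%, both below every Biowire library (exact p = 0.1 each, the smallest that 3 against 3 allow), and a TNNI3 share of 9.37 ± 3.78% (exact p = 0.7). The tables were counted separately, and the labels give no culture day for the digested cells.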
